A study of Homo sapiens with 3 samples.

How the data were processed

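RNA sequencing had been carried out on 3 libraries labelled Huh-7, a human hepatocellular carcinoma cell line, all labelled 48 h. Of these, 1 library was labelled si-NC and 2 were labelled siRNA, with the names siRNA-1 and siRNA-3. si-NC was taken as the control. The labels do not name the target of the siRNAs, do not say whether siRNA-1 and siRNA-3 are different reagents, and do not say whether the libraries came from separate cultures. Any p-value therefore measures only the spread between these samples, which may be technical. Per the labels' protocols, total RNA was extracted with TRIzol and libraries were made with an Illumina TruSeq RNA kit. The use of strand in counting is not given in the sources used here.

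The deposited table holds TPM, a share of transcripts scaled by gene length and to a common total, for 61871 genes in the 3 libraries, made by the authors and rounded to 2 decimals. HISAT2, StringTie, RSEM and the build hg38 are named, per the submitters' processing notes, without versions or roles. The deposited gene length in bases is of another kind and was used only to sort genes into shorter and longer ones. Each library summed to the same total by construction, so the sequencing depth is unknown and no counting interval or detection floor can be given. A value of 0 in the table can also be a failed estimate, so such a gene is described as listed at 0, and no fold change is printed for it. The value of each library is given for some of these genes only. Genes listed at 0 still enter the rankings, the limma fits, the counts by size and the plotted fold changes. Of the row identifiers, 61541 were Ensembl gene identifiers and 330 were identifiers from transcript assembly. GENCODE release 29 matched 58366 identifiers and gave gene types, GC content and GRCh38 coordinates. Gene symbols came from the table.

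Values were analysed as log2(TPM + 1), and genes with a mean of at least 1 TPM over the 3 libraries were kept, which left 15501 genes, 12007 of them protein-coding. A fold change on this scale understates the change of genes of low abundance. The 2 siRNA libraries were compared with the si-NC library with limma-trend (limma 3.58.1 in R 4.3.3, lmFit and eBayes with a trend, two-sided, Benjamini-Hochberg adjusted p under 0.05). This fit has 1 residual degree of freedom. Its residual spread comes from the difference between siRNA-1 and siRNA-3, which may be 2 different reagents. The lone si-NC library is assumed to vary alike. eBayes then draws the spread of each gene towards a trend over all genes, with a median of 2.45 prior degrees of freedom. Each limma SE and p-value therefore rests in large part on other genes. An exact permutation test of 3 libraries split into 2 and 1 cannot give a p below 0.333, so none was run. Each siRNA library was also compared with si-NC and with the other siRNA library by size alone, with a threshold of 2-fold and no test, since each side is 1 library.

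Both comparisons with si-NC share that library, so their overlap and correlation lie above 0 without any effect. The values for unchanged libraries with a shared control were obtained from 100 simulated sets of 3 libraries, with noise taken from the difference between siRNA-1 and siRNA-3. That noise holds any real difference between these libraries, so the simulated values may be too high. With 1 control library, the control could not be split, and part of any excess may come from it.

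Before the data were examined, 28 gene lists were fixed. A list with at least 5 measured members was described by the median log2 fold change of its members in each siRNA library, and by the percentile of that median among 10000 random lists of the same size matched on mean expression in 20 bins. A list stood apart when both percentiles were outside 2.5 to 97.5 on the same side. The same was done for the KEGG pathways and GO biological processes in the deposited table with 10 to 300 measured genes, with limits of 0.5 and 99.5. These percentiles describe the libraries and are not p-values.

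Genes were named by a rule fixed before the data were examined. It takes the transcript of the series title and the measured SLC1A5 locus genes. It takes the 12 genes higher and the 12 lower in both siRNA libraries with the largest smaller change among genes with a symbol and a mean of at least 5 TPM. It takes up to 4 members of each list with the largest smaller change in the same direction in both libraries, the 5 genes on each side with the largest difference between siRNA-1 and siRNA-3, and up to 2 members of each term. Short genes filled most of these places, so the ranking by change and the ranking by difference were repeated among protein-coding genes (12 and 8 per direction) after the values had been seen. Further members of several lists were also named after their values were seen, as the text states.

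The alternatives were pseudocounts of 0.1 and 5, no filter on low values, a mean of at least 5 TPM, median-of-ratios scaling, quantile normalization, eBayes without a trend, robust eBayes, protein-coding genes alone, thresholds of 1.5-fold and 3-fold, and leaving out each siRNA library. The restriction to protein-coding genes for results other than the limma count, the removal of a GC trend in 20 bins of GC content and the repeated naming rules were added after seeing the data.

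The scripts were tested on simulated data with 200 seeded genes, for the comparison of 2 siRNA libraries with 1 si-NC library. Among 15501 genes with noise resampled from these libraries, limma-trend recovered 0% of genes seeded at a log2 change of 1, 48% at 2, 84% at 3 and 84% at 4, and called 43 unchanged genes. Among the 12007 protein-coding genes it recovered 24% at a log2 change of 1 and 100% at 2, 3 and 4, with 31 unchanged genes called. With normal noise over 15501 genes the shares were 52% at 1 and 100% at the larger changes, with 11 unchanged genes called. All these shares hold with 200 changed genes seeded at once, which can ease the Benjamini-Hochberg adjustment. They do not give the share recovered in the real data, where 0 of 15501 genes passed at the main settings. There TMEFF2, listed at 0 in si-NC, was at 25.2 TPM in siRNA-1 and 30.4 TPM in siRNA-3, with a limma adjusted p of 0.138. The resampled noise was heavier-tailed than the model assumes, and adjusted p-values near the threshold were too small to that extent in this simulation. Whether they are too small or too large in the real data was not tested. Of simulated lists of 20 protein-coding genes, ranked against 15501 genes, 0% stood above the 97.5 percentile in both libraries with no shift. The share was 40% with a log2 shift of 0.2 and 98% with a shift of 0.4. All 100 lists at a given shift used a single draw of noise, so these shares do not cover the variation between draws. Noise was drawn for each gene on its own, and only the upper limit was tested. Members of real lists may vary together, so the 0% does not give the rate at which unchanged real lists would stand apart. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. Sample columns outside these 3 libraries were not present, and levels of XIST and of Y-linked genes are not reported. Values of some genes that the naming rules take are not reported here.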

Results

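Gene expression was measured by RNA sequencing in 3 libraries labelled Huh-7, a hepatocellular carcinoma line, of which 1 carried a control siRNA label (si-NC) and 2 carried siRNA labels (siRNA-1 and siRNA-3), all at 48 h. The series concerns a long non-coding RNA named SLC1A5-AS, glutamine uptake, hypoxia and ASCT2, the glutamine transporter encoded by SLC1A5. Values are TPM, with 25427 genes above 0 in si-NC, 25405 in siRNA-1 and 24756 in siRNA-3. The 10 most abundant genes held 12.25% of all TPM in si-NC, 12.1% in siRNA-1 and 11.7% in siRNA-3. There was 1 library per label, so values carry no replicate error except where limma treated the 2 siRNA libraries as replicates. Of 20 genes for hepatocyte secreted proteins and liver transcription factors, 17 were below 1 TPM in all 3 libraries, and the cell line is therefore given as labelled.

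The first question was whether the transcript of the series title was lower in the siRNA libraries. The antisense gene annotated at the SLC1A5 start was lower in both, at 2.29 TPM in si-NC, 0.40 TPM in siRNA-1 and 0.73 TPM in siRNA-3. SLC1A5 itself was at 266 TPM in si-NC, 285 TPM in siRNA-1 and 199 TPM in siRNA-3, log2 fold changes of 0.10 and -0.42. The antisense gene is AC008622.2 (ENSG00000275719), on the plus strand of chromosome 19 from 46787815 to 46789043 in GRCh38. Its annotated transcripts have a single exon each. They share 780 bases with the SLC1A5 exon from 46787400 to 46788594, which holds the start codon at 46787963 to 46787965, on the minus strand. SLC1A5 (ENSG00000105281) spans 46774883 to 46788594. No gene in the table carried the name SLC1A5-AS, and AC008622.2 was taken by its position alone. Reads of the overlap cannot be assigned to a strand unless the counting used it, which is not stated. The mean log2 fold change of AC008622.2 was -1.08 (limma SE 0.31, limma adjusted p = 1). It was -1.89 with a pseudocount of 0.1 and -0.39 with a pseudocount of 5.

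**Figure D1:**
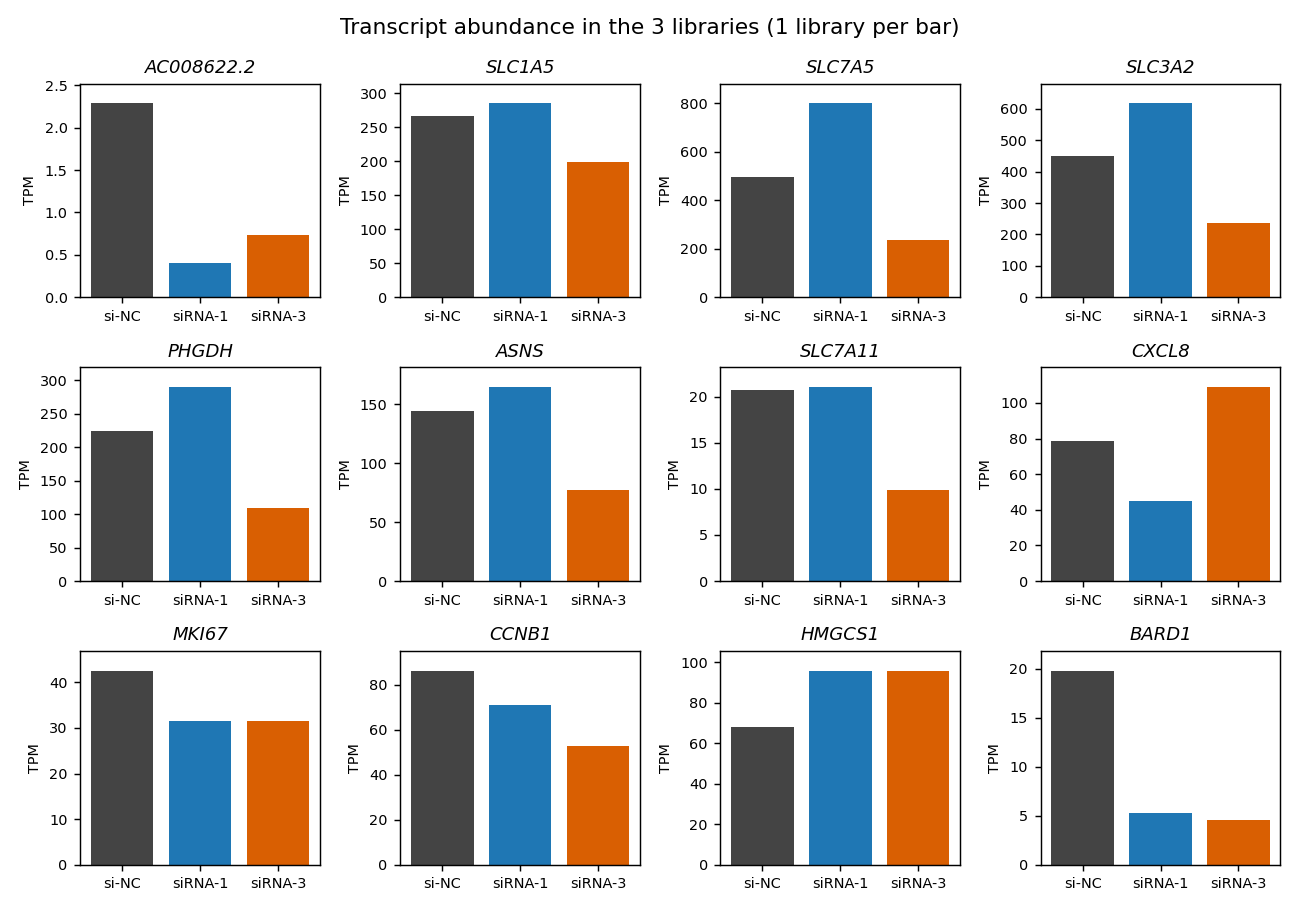
TPM (vertical axes, linear, from 0) of 12 genes in si-NC, siRNA-1 and siRNA-3, with 1 library per bar and no error bars. AC008622.2 and BARD1 were lower in both siRNA libraries, while SLC7A5 was at 801 TPM in siRNA-1 and 236 TPM in siRNA-3, on either side of 497 TPM in si-NC.

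Of 12 measured genes of the SLC1A5 locus on 19q13, 6 were above si-NC in siRNA-1 and below it in siRNA-3, 3 were higher in both and 2 lower in both. The median log2 fold change was 0.10 in siRNA-1 (percentile 90.4 of matched random lists) and -0.17 in siRNA-3 (percentile 3.77), and the median difference between the siRNA libraries was 0.32 (percentile 99.7). TMEM160 was at 35.5 TPM in si-NC, 44.4 TPM in siRNA-1 and 40.2 TPM in siRNA-3. BBC3, a pro-apoptotic gene, was at 24.6, 33.5 and 26.7 TPM in the same order. STRN4 was at 65.7, 70.3 and 70.1 TPM. AP2S1, a subunit of the clathrin adaptor, was at 221, 200.4 and 160.0 TPM. CALM3, which encodes calmodulin, was at 124, 123 and 77.7 TPM. PRKD2 was at 25.6, 21.2 and 26.8 TPM, ZC3H4 at 7.79, 7.90 and 6.43 TPM, NPAS1 at 2.08, 2.93 and 1.94 TPM and SAE1 at 104, 106 and 93.2 TPM. ARHGAP35 was at 20.8, 26.1 and 18.1 TPM. In this list 0 members passed limma over all genes and 0 passed adjusted over the list alone.

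Both siRNA libraries against si-NC gave the genes that differed in common. Among protein-coding genes with a mean of at least 5 TPM, BARD1, a partner of BRCA1 in DNA repair, was lower at 19.8 TPM in si-NC, 5.33 TPM in siRNA-1 and 4.60 TPM in siRNA-3. TMEFF2, a transmembrane protein gene, was listed at 0 in si-NC and was at 25.2 TPM in siRNA-1 and 30.4 TPM in siRNA-3. ATAD3B, which encodes a mitochondrial ATPase, was higher at 10.3, 20.9 and 25.8 TPM. None of these passed limma over all genes tested.

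The mean log2 fold change of BARD1 was -1.80 (limma SE 0.23, limma adjusted p = 0.524). ESCO2, an acetyltransferase of sister chromatid cohesion, was at 15.2 TPM in si-NC, 5.39 TPM in siRNA-1 and 7.12 TPM in siRNA-3. ELOVL6, a fatty acid elongase, was at 12.8, 6.23 and 6.13 TPM. NRP2, a semaphorin and VEGF co-receptor, was at 7.87, 3.95 and 3.35 TPM, and HOXA3 was at 9.06, 4.71 and 4.36 TPM. Further protein-coding genes among the 12 that were lowest were SNURF, MAPKBP1, EID2B, METTL7A, CYSRT1 and ZNF778, with mean log2 fold changes from -1.25 for SNURF to -0.86 for EID2B. On the higher side, KDM2B, a histone demethylase, was at 9.18, 16.8 and 17.5 TPM. HABP4 was at 3.29, 7.64 and 8.14 TPM, MXRA8 at 3.15, 7.30 and 8.18 TPM, and RPP40, a subunit of ribonuclease P, at 4.35, 8.69 and 9.50 TPM. ZNF616, ZFP1, H2BC18, SULT1A4, RGS19 and ZNF254 completed the 12, with mean log2 fold changes from 0.79 for RGS19 to 1.19 for SULT1A4. SULT1A4 has a near-identical copy and SNURF shares its transcripts with SNRPN, so their values are uncertain. This ranking of protein-coding genes was chosen after the values had been seen.

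**Figure D2:**
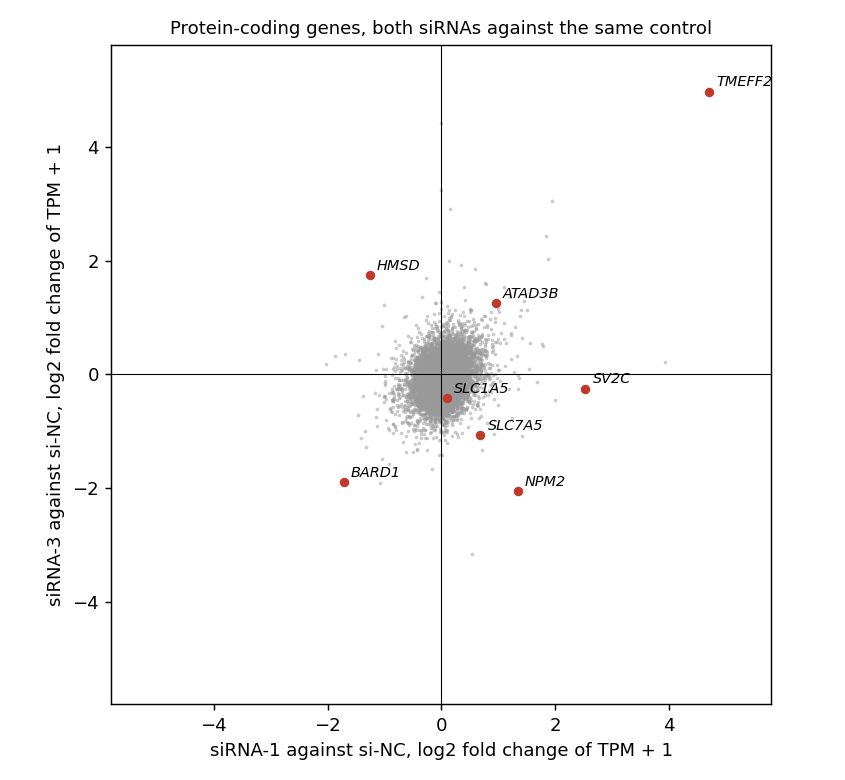
Log2 fold change of TPM + 1 against si-NC in siRNA-1 (horizontal axis) and siRNA-3 (vertical axis) for protein-coding genes, 1 grey point per gene, with named genes in red. BARD1 lies low on both axes, TMEFF2, listed at 0 in si-NC, lies high on both, and SV2C and HMSD lie far from the diagonal.

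Over all gene types, 12 of the 12 genes that were lowest in both siRNA libraries were shorter than 300 bases, and 4 of the 12 that were highest were. On the lower side 10 genes were listed at 0 in both siRNA libraries. They were 5 Y RNA copies, RNY1P13, RNA5S17, SNORA10, SNORA15 and SCARNA15, with si-NC values from 15.3 to 81.6 TPM. The pseudogenes CDC26P1 and PSMC1P5, each above 0 in siRNA-1, completed the 12. On the higher side, RDXP2, TMEFF2, SNORA20 and SNORA21B were listed at 0 in si-NC. SLC7A5P2, a pseudogene of the amino acid transporter SLC7A5, was at 0.82 TPM in si-NC, 8.09 TPM in siRNA-1 and 8.05 TPM in siRNA-3. Reads of the far more abundant SLC7A5 may be counted for it, so its values are uncertain. SRP9P1, LINC01399, GPRC5D-AS1 and LINC02699 were the other non-coding genes among the 12. Genes shorter than 300 bases differed at least 2-fold from si-NC in 51.0% of 394 cases in siRNA-1 and 53.05% in siRNA-3, and differed between siRNA-1 and siRNA-3 in 49.0%. Among 15107 longer genes the shares were 1.52%, 1.75% and 2.43%.

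With limma-trend, 0 of 15501 genes passed an adjusted p of 0.05. Fewer genes had an unadjusted p under 0.05 than evenly spread p-values would give. The smallest adjusted p was 0.136. TMEFF2 passed among protein-coding genes alone and with robust eBayes. It was listed at 0 in si-NC and was at 25.2 TPM in siRNA-1 and 30.4 TPM in siRNA-3. The other genes that passed with robust eBayes were all shorter than 300 bases. Each gene that passed in any setting of this comparison was listed at 0 in si-NC or in both siRNA libraries. These calls therefore rest on values that may be failed estimates. RDXP2, of 111 bases, was the 1 gene past the threshold among genes with a mean of at least 5 TPM (limma adjusted p = 0.0421).

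By size alone, 70 genes were at least 2-fold higher in both siRNA libraries than in si-NC and 97 were at least 2-fold lower. Unchanged libraries that share 1 control gave 129.5 and 128.4 such genes in simulation, and independent lists gave 3.3 and 3.2. Among protein-coding genes 13 were higher and 6 lower, beside 22.1 and 21.4 simulated. Across genes, which are not independent replicates, the log2 fold changes of the 2 siRNA libraries had a Pearson r of 0.43 and a Spearman rho of 0.25, beside a simulated r of 0.50. Their covariance was 0.118, beside 0.157 simulated (0.141 to 0.182 over 100 draws), a difference of -0.04. In protein-coding genes r was 0.31 and the covariance 0.029, beside 0.068 simulated. An r near 0.50 follows from libraries of equal noise with a shared control, and the simulated covariance follows from the spread between siRNA-1 and siRNA-3. Observed values below them restate that this spread was wider than that of either siRNA library against si-NC. The overlap on the lower side exceeded the simulated one without a filter on low values, with 206 genes beside 159.7, and with a pseudocount of 5, with 62 genes beside 51.7. On the higher side these settings gave 79 genes beside 160.1 and 15 genes beside 49.8. The simulated noise has equal signs and no floor at 0. At the main settings the lower side was also larger with another library as the lone one. With siRNA-1 alone, 66 genes were at least 2-fold higher in both others and 120 lower, and with siRNA-3 alone 96 and 109. In total these were 186 and 205 genes, beside 167 with si-NC alone, and 36 and 51 beside 19 among protein-coding genes.

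Of 18 measured G2 and M phase genes, 13 were lower in both siRNA libraries and 5 were above si-NC in siRNA-1 and below it in siRNA-3, with a median log2 fold change of -0.12 in siRNA-1 (percentile 0.51) and -0.42 in siRNA-3 (percentile 0). The median difference between the siRNA libraries was 0.30 (percentile 99.91). MKI67, the gene of the proliferation antigen Ki-67, was at 42.5 TPM in si-NC, 31.4 TPM in siRNA-1 and 31.5 TPM in siRNA-3. CCNB1, the mitotic cyclin B1, was at 86.3, 71.0 and 52.96 TPM. The mitotic kinesins KIF20A and KIF11 were at 22.8, 16.7 and 12.3 TPM and at 12.6, 9.75 and 8.20 TPM. TOP2A, named after its values were seen, was at 69.7, 74.8 and 39.5 TPM. In this list 0 members passed limma over all genes and 0 adjusted over the list alone. The S phase genes did not go with them in siRNA-3. Over 18 members the median was -0.13 in siRNA-1 (percentile 0.18) and 0.02 in siRNA-3 (percentile 65.3), with 5 members higher and 5 lower in both. CCNE2 was at 3.89, 2.49 and 2.20 TPM, CDC6 at 27.8, 23.8 and 21.8 TPM, GINS2 at 16.4, 19.9 and 22.8 TPM and UHRF1 at 32.7, 28.99 and 29.1 TPM.

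Interferon-stimulated genes were the other list that stood apart on the same side in both libraries. Their median over 16 members was -0.21 in siRNA-1 (percentile 0.06) and -0.35 in siRNA-3 (percentile 0), although only 6 members were lower in both. OAS3 was at 35.0 TPM in si-NC, 27.4 TPM in siRNA-1 and 28.5 TPM in siRNA-3, IFIT3 at 6.81, 5.72 and 4.12 TPM, IFIT2 at 5.44, 4.63 and 2.17 TPM and IFI44L at 3.66, 3.01 and 2.49 TPM. ISG15, an abundant member named after its values were seen, was at 363, 482 and 237 TPM, higher in siRNA-1. The list no longer stood apart without a filter on low values, where the median over 22 members was 0.01 in siRNA-1 (percentile 46.4), or among genes with a mean of at least 5 TPM, where the percentile in siRNA-3 was 2.73. In this list 0 members passed limma over all genes and 0 adjusted over the list alone.

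**Figure D3:**
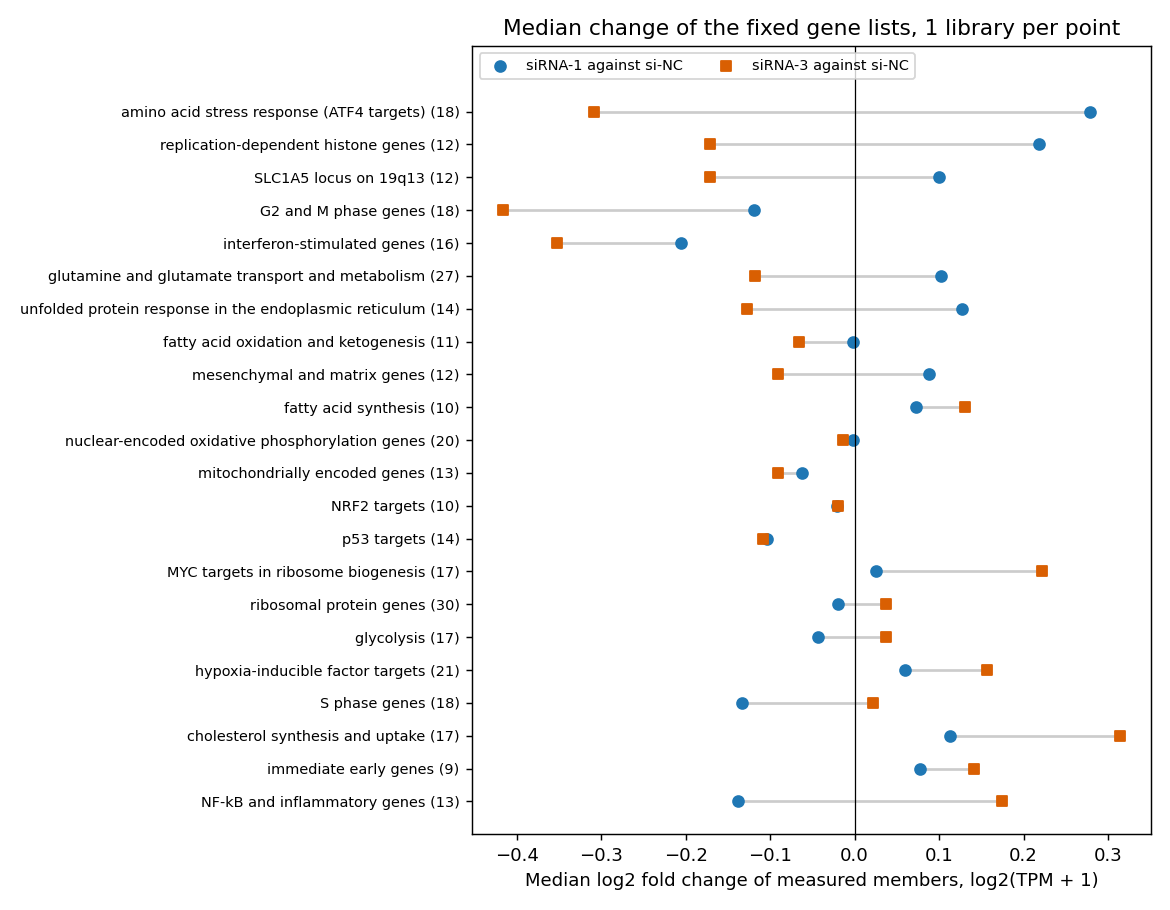
Median log2 fold change of TPM + 1 against si-NC (horizontal axis) of the 22 gene lists with at least 5 measured members, in siRNA-1 (blue circles) and siRNA-3 (orange squares), with the number of measured members in brackets and the lists ordered by the median difference between the 2 libraries. ATF4 targets lie at 0.28 and -0.31, and G2 and M phase genes lie at -0.12 and -0.42.

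Between siRNA-1 and siRNA-3, amino acid and inflammatory genes differed in opposite senses. Of 18 genes in the ATF4 target list, 15 were above si-NC in siRNA-1 and below it in siRNA-3. The list includes ATF4, the transcription factor of the amino acid stress response. The median log2 fold change was 0.28 in siRNA-1 (percentile 100) and -0.31 in siRNA-3 (percentile 0.01), and the median difference between the 2 libraries was 0.67. PHGDH, the first enzyme of serine synthesis, was at 225 TPM in si-NC, 290.0 TPM in siRNA-1 and 109 TPM in siRNA-3. ASNS, asparagine synthetase, was at 145, 165 and 77.3 TPM, and TRIB3, a pseudokinase, at 80.8, 139 and 62.6 TPM. PSAT1 was at 119, 151 and 80.0 TPM and DDIT3 at 43.7, 60.4 and 32.0 TPM. ATF4 mRNA, counted among the 15, was at 481, 525 and 438 TPM. The members that went the same way in both libraries were CHAC1 at 20.01, 18.9 and 11.5 TPM, SHMT2 at 390.1, 381 and 360 TPM and CEBPB at 86.0, 99.9 and 89.2 TPM. Members beyond these 3 were named after their values were seen, and the difference of 1 library from 1 other has no replicate check. In this list 0 members passed limma over all genes and 0 adjusted over the list alone.

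Of 27 measured genes of glutamine and glutamate transport and metabolism, the process in the series title, 14 were above si-NC in siRNA-1 and below it in siRNA-3, 6 were higher in both and 5 lower in both. Medians were 0.10 in siRNA-1 (percentile 98.1) and -0.12 in siRNA-3 (percentile 3.65). SLC7A5 and SLC3A2, the 2 chains of a large neutral amino acid exchanger, were at 497, 801 and 236 TPM and at 449, 618 and 237 TPM in si-NC, siRNA-1 and siRNA-3. SLC7A11, the cystine and glutamate exchanger, was at 20.8, 21.1 and 9.83 TPM. GLUL, glutamine synthetase, was at 55.0, 57.6 and 63.8 TPM. These 4 were named after their values were seen. Chosen by the planned rule, CTPS1 was at 50.4, 54.3 and 60.6 TPM, ALDH18A1 at 39.9, 42.2 and 52.3 TPM, GCLC at 22.5, 20.9 and 19.2 TPM and GLS2 at 1.79, 1.27 and 1.33 TPM. The list shares ASNS, PSAT1 and SLC7A11 with the fixed ATF4 target list, and these were not left out. Whether further members, such as SLC7A5 and SLC3A2, also answer to ATF4 was not assessed. The pattern here may therefore be the same as that of the ATF4 target list. Again 0 members passed limma over all genes and 0 adjusted over the list alone.

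Of 13 measured NF-kB and inflammatory genes, 9 were below si-NC in siRNA-1 and above it in siRNA-3. Medians were -0.14 (percentile 1.22) and 0.17 (percentile 98.8), and the median difference between the siRNA libraries was -0.53. CXCL8, the chemokine interleukin-8, was at 78.7 TPM in si-NC, 44.9 TPM in siRNA-1 and 109 TPM in siRNA-3. NFKBIA, the inhibitor of NF-kB, was at 152, 121 and 186 TPM, and ICAM1 at 33.6, 20.6 and 35.6 TPM; these 3 were named after their values were seen. IL6 was at 10.5, 11.3 and 16.1 TPM, BIRC3 at 125, 119 and 114 TPM and CCL20 at 1.16, 1.17 and 2.39 TPM. LCN2 had log2 fold changes of 0.20 in siRNA-1 and 0.01 in siRNA-3. Targets of the unfolded protein response had medians of 0.13 in siRNA-1 (percentile 97.2) and -0.13 in siRNA-3 (percentile 8.22) over 14 members, with DNAJB9 at 15.8, 13.2 and 13.6 TPM and MANF at 66.9, 73.2 and 68.9 TPM. Histone genes had medians of 0.22 in siRNA-1 (percentile 98.7) and -0.17 in siRNA-3 (percentile 8.72) over 12 members. The siRNA-3 median was -0.06 among protein-coding genes alone (percentile 39.4) and 0.01 after removal of a GC trend (percentile 52.1). H2BC8 was at 4.71, 2.89 and 2.63 TPM and H1-2 at 39.2, 46.6 and 45.6 TPM. Each of these 3 lists had 0 members past limma over all genes and 0 adjusted over the list alone.

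Single genes that set siRNA-1 and siRNA-3 apart were often near si-NC in one of them. Among protein-coding genes, ranked so after the values were seen, SV2C, a synaptic vesicle protein, was at 5.08 TPM in si-NC, 34.2 TPM in siRNA-1 and 4.11 TPM in siRNA-3. PRRT2 was at 0.26, 18.3 and 0.47 TPM, NPM2 at 6.78, 18.7 and 0.88 TPM, and SPINT2, a protease inhibitor, at 10.7, 26.6 and 5.83 TPM. CPA4 was at 21.8, 36.6 and 8.03 TPM and RNF170 at 3.91, 14.8 and 3.49 TPM. HMSD was at 7.84, 2.70 and 28.7 TPM, TMEM52 at 4.55, 3.59 and 17.1 TPM, MAPK15 at 4.38, 4.92 and 20.5 TPM and BAIAP3 at 4.76, 1.81 and 9.45 TPM. UBD, an inflammation-induced ubiquitin-like protein, was at 10.5, 3.23 and 12.6 TPM. PTGDS and C9orf116 were also higher in siRNA-3, and GAGE12B, GAGE12C and NPIPA8 belong to families of near-identical copies and are uncertain. Over all gene types, the 5 genes farthest apart on each side were all shorter than 300 bases and listed at 0 in 2 of the 3 libraries. They were MIR671, RNU6-31P, SNORA31, RNU5A-4P and a Y RNA copy in siRNA-1, and RNA5S10, RNU6-105P, RNU6-999P and 2 Y RNA copies in siRNA-3.

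The 2 siRNA libraries differed from each other in more genes than either did from si-NC. At least 2-fold differences numbered 430 in siRNA-1 against si-NC (235 higher, 195 lower), 473 in siRNA-3 against si-NC (220 higher, 253 lower) and 560 between siRNA-1 and siRNA-3 (328 higher and 232 lower in siRNA-1). Among 12007 protein-coding genes they numbered 78, 113 and 168. At 3-fold the order did not hold, with 228, 237 and 234 genes. The balance of higher and lower genes depended on scaling. With quantile normalization it turned to 246 higher and 221 lower in siRNA-3 against si-NC. Between the siRNA libraries it turned to 265 higher and 276 lower in siRNA-1, and it was 289 and 267 with median-of-ratios scaling.

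Targets of the hypoxia-inducible factor had medians of 0.06 in siRNA-1 (percentile 84.1) and 0.16 in siRNA-3 (percentile 99.54) over 21 members, 10 of them higher and 1 lower in both. VEGFA was at 179 TPM in si-NC, 216 TPM in siRNA-1 and 205 TPM in siRNA-3, ANKRD37 at 21.3, 24.7 and 38.5 TPM, LOX at 31.2, 34.6 and 34.3 TPM and ANGPTL4 at 61.9, 45.7 and 46.7 TPM. Cholesterol synthesis and uptake genes had medians of 0.11 (percentile 96.4) and 0.31 (percentile 100), with 13 of 17 members higher in both. HMGCS1, which makes the substrate of HMG-CoA reductase, was at 68.0, 95.5 and 95.8 TPM, FDPS at 192, 228 and 226 TPM, CYP51A1 at 32.5, 37.9 and 43.3 TPM and SQLE at 17.5, 20.7 and 20.3 TPM. With quantile normalization this list stood apart in both libraries (percentiles 97.6 and 100). Fatty acid synthesis genes had medians of 0.07 (percentile 79.6) and 0.13 (percentile 94.6) over 10 members, with FASN, fatty acid synthase, at 64.9, 74.5 and 114 TPM, ACACA at 25.0, 31.4 and 27.99 TPM, ME1 at 9.09, 12.9 and 11.1 TPM and ELOVL6 lower, as above. MYC targets in ribosome biogenesis, with MYC itself in the list, had medians of 0.03 (percentile 66.0) and 0.22 (percentile 99.95) over 17 members. With median-of-ratios scaling the median in siRNA-1 was no longer above 0. MYC was at 359, 449 and 424 TPM, NOLC1 at 64.1, 89.4 and 83.9 TPM, NCL at 154, 182 and 180.2 TPM and BOP1 at 50.1, 55.8 and 72.7 TPM. In these 4 lists 0 members passed limma over all genes and 0 adjusted over the list alone.

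Medians of the remaining lists with at least 5 measured members lay within the percentile limits in each siRNA library at the main settings. Glycolysis genes were at -0.04 in siRNA-1 and 0.04 in siRNA-3 over 17 members, the latter 0 with quantile normalization, with PFKL at 44.1 TPM in si-NC, 60.8 TPM in siRNA-1 and 76.3 TPM in siRNA-3. Targets of p53 were at -0.10 and -0.11 over 14 members, with CDKN1A, the cell cycle inhibitor p21, at 74.7, 58.3 and 47.9 TPM and MDM2 at 20.3, 24.1 and 24.4 TPM. The siRNA-1 median of this list was 0.02 among genes with a mean of at least 5 TPM, and its percentile was 1.84 with quantile normalization and 2.37 after removal of a GC trend. NRF2 targets were at -0.02 and -0.02 over 10 members, the latter 0.02 with median-of-ratios scaling, with TXNRD1, thioredoxin reductase, at 204, 134 and 146 TPM and HMOX1 at 18.8, 24.1 and 31.3 TPM. Fatty acid oxidation genes were at -0.0021 and -0.07 over 11 members, with CPT1A at 44.2, 49.3 and 58.3 TPM. Mesenchymal and matrix genes were at 0.09 and -0.09 over 12 members, with TWIST1 at 9.82, 6.92 and 7.13 TPM. Nuclear-encoded oxidative phosphorylation genes were at -0.0023 and -0.01 over 20 members, the latter 0.03 with median-of-ratios scaling, with SDHB at 86.5, 103 and 102 TPM. Mitochondrially encoded genes were at -0.06 and -0.09 over 13 members and held 9.54% of TPM in si-NC, 8.99% in siRNA-1 and 9.03% in siRNA-3. Ribosomal protein genes were at -0.02 and 0.04 over 30 members, the former 0 with quantile normalization, with RPL4 at 5570.1, 5362 and 3592 TPM. Immediate early genes were at 0.08 and 0.14 over 9 members, with IER2 at 125, 135 and 138 TPM, and the siRNA-1 median was -0.06 among genes with a mean of at least 5 TPM. Their median difference between siRNA-1 and siRNA-3 was -0.37 (percentile 0.13). None of these lists had a member past limma, over all genes or adjusted over the list alone.

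The design text of the series names enriched pathways and processes. Of 1938 annotated terms (318 KEGG pathways and 1620 GO processes), 3 stood lower in both siRNA libraries and 0 higher, and all 3 concern endosomes, phagosomes or lysosomes. Transferrin transport had a median of -0.15 in siRNA-1 and -0.25 in siRNA-3 over 27 genes. The Phagosome pathway was at -0.07 and -0.12 over 87 genes, and the Lysosome pathway at -0.10 and -0.10 over 110 genes. LAMP1, a lysosomal membrane protein counted in both pathways, was at 56.9 TPM in si-NC, 42.3 TPM in siRNA-1 and 22.3 TPM in siRNA-3. The proton pump subunits ATP6V1G2 and ATP6V1C2 were at 5.26, 3.87 and 2.15 TPM and at 1.89, 0.75 and 1.20 TPM. Against the direction of their terms, AP1M2 was at 13.5, 30.1 and 21.4 TPM and EEA1 at 3.81, 5.85 and 5.82 TPM. Terms share genes. Neither the Lysosome nor the Phagosome pathway stood apart with a pseudocount of 5, among genes with a mean of at least 5 TPM or among protein-coding genes alone. The Phagosome pathway did not without a filter on low values, nor the Lysosome pathway with quantile normalization.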

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

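Protein-coding results other than the limma count, and the GC removal, were chosen after seeing the data. Unless a value below shows the cause by its construction (other thresholds, fewer or more genes, fewer libraries), the cause was not tested. The limma count of 0 became 1 among genes with a mean of at least 5 TPM, 1 among protein-coding genes and 10 with robust eBayes, and stayed 0 with the other alternatives. Counts of at least 2-fold differences are given for siRNA-1 against si-NC, siRNA-3 against si-NC, siRNA-1 against siRNA-3, and both siRNAs in the same direction. They were 735, 868, 1032 and 299 with a pseudocount of 0.1, and 161, 175, 202 and 77 with a pseudocount of 5. They were 127, 167, 244 and 46 with a mean of at least 5 TPM, and 78, 113, 168 and 19 among protein-coding genes. Without a filter they were 697 and 759 for the siRNA libraries against si-NC and 285 in both. At 1.5-fold they were 1180, 1589, 2056 and 412, and at 3-fold 228, 237, 234 and 107. The balance of genes higher and lower in both, 70 and 97, became 151 and 148 with a pseudocount of 0.1, 15 and 62 with a pseudocount of 5, 79 and 206 without a filter, 17 and 29 with a mean of at least 5 TPM, 13 and 6 among protein-coding genes, 193 and 219 at 1.5-fold and 29 and 78 at 3-fold. With 1 siRNA library left out, the count in both is that of the other library, 430 to 473, and limma has no residual degree of freedom and was not run. The correlation across genes was 0.48 with a pseudocount of 0.1, 0.38 with a pseudocount of 5, 0.45 without a filter, 0.37 with a mean of at least 5 TPM and 0.31 among protein-coding genes. Gene lists apart on the same side numbered 1 without a filter and 1 with a mean of at least 5 TPM, in each case the G2 and M phase genes, and 7 to 7 with 1 siRNA library left out. Terms numbered 1 with a mean of at least 5 TPM, transferrin transport, and 54 to 55 with 1 siRNA library left out, when only 1 percentile had to pass. The mean log2 fold change of AC008622.2 was -1.89 with a pseudocount of 0.1 and -0.39 with a pseudocount of 5. Of the other alternatives to these summary results, 33 stayed within the limits set for a change. Of those for single genes, lists and terms, 1654 moved by less than 1 SD of the siRNA libraries and 177 by more, most of them with another pseudocount. That SD is taken from the 2 siRNA libraries themselves and is widest where they disagree. Leaving out 1 of them moves a value by less than 1 SD almost by construction, even where its sign turns, as in the ATF4 target list. The count of 1654 therefore does not measure stability. No paired analysis was possible because the control is 1 library and its label carries no replicate number. The depth is unknown, so no limit from counting can be given. With the control in 1 library, its own noise enters every comparison with si-NC.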

Other observations

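The tests in this part were chosen, and the genes in it named, after the results had been seen. Genes of liver function were close to 0 in the libraries labelled Huh-7. ALB, APOH, TTR, SERPINA1, AHSG, AMBP and FOXA2 were listed at 0 in all 3 libraries, and AFP, the oncofetal marker of hepatocellular carcinoma, was at 0.03 TPM in si-NC and listed at 0 in the siRNA libraries. The 3 measured members of the hepatocyte list were RBP4 at 10.9 TPM in si-NC, 9.83 TPM in siRNA-1 and 12.9 TPM in siRNA-3, CEBPA at 6.55, 6.45 and 6.18 TPM and HNF4A at 1.62, 2.41 and 2.30 TPM. Of 14 acute phase and complement genes, 4 were measured, namely C3 at 309, 281 and 375 TPM, CFB at 54.0, 49.8 and 39.7 TPM, C4A at 2.06, 1.42 and 1.58 TPM and C5 at 1.71, 0.61 and 1.38 TPM. C4A has a near-identical copy and is uncertain. Lists with under 5 measured members were given no percentile, and 0 of their members passed limma.

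KRT7, a keratin of simple epithelia and of bile ducts, was at 663 TPM in si-NC, 846 TPM in siRNA-1 and 689 TPM in siRNA-3, while the other cholangiocyte markers KRT19, SOX9 and CFTR were at most 0.18 TPM and EPCAM was at 6.03, 11.1 and 9.41 TPM. VIM, vimentin, was at 896, 880.1 and 1068 TPM, and ITGA5 and TGFBI, also of the mesenchymal list, were lowest at 163 TPM, for TGFBI in siRNA-3. Of 7 fibroblast and stellate cell markers 4 were measured, with LUM at 34.1, 24.5 and 40.3 TPM, DCN at 5.09, 13.7 and 5.30 TPM, COL1A1 at 5.91, 11.9 and 8.66 TPM and ACTA2 at 2.14, 3.98 and 2.47 TPM, while COL1A2 was listed at 0. Of 5 endothelial markers PECAM1 alone was measured, at 4.61, 1.78 and 3.32 TPM. Of 10 blood and immune markers 3 were measured, among them CD68 at 32.8, 27.6 and 33.3 TPM and HBA1 listed at 0 in si-NC and at 1.14 and 1.90 TPM in the siRNA libraries. HBA1 has a near-identical copy and is uncertain.

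The near absence of liver transcripts does not go with a failure of estimates over the whole table. Of 28 genes used by every cell, 0 were under 1 TPM in any library and the lowest was at 11.96 TPM. These genes cannot show whether estimates failed for single genes, such as the 7 hepatocyte genes listed at 0 in all 3 libraries. APOA1 and TF were above 0 in each library, at no more than 0.15 and 0.19 TPM. Huh-7 cells are known as producers of albumin and alpha-fetoprotein. Cells other than those the label names, or a culture of Huh-7 that had lost these transcripts, could both give values such as the 17 of 20 hepatocyte genes under 1 TPM in all 3 libraries. That count is the pattern itself and does not decide between them, so they cannot be told apart.

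The opposite positions of siRNA-1 and siRNA-3 in the ATF4 target list were weighed next. The median difference between the 2 libraries was 0.67 before any correction and 0.67 after a trend with GC content had been removed, and 0.59 after quantile normalization, which argues against a GC trend or scaling as the whole cause. The state of each culture at harvest, such as amino acid supply or density, may raise or lower these genes, and with 1 library per siRNA it cannot be told apart from an effect of the siRNA sequence.

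Short genes led the planned rankings, and a candidate explanation is noise of short genes in each library. It predicts that they differ as often between siRNA-1 and siRNA-3 as against si-NC, and 49.0% of 394 did (95% Wilson interval 44.1% to 53.9%, which covers counting error only), beside 51.0% in siRNA-1 against si-NC. Transcripts of at least 5 TPM in 1 library that were listed at 0 in both others numbered 46 in si-NC, 37 in siRNA-1 and 41 in siRNA-3 among these genes. Whether the siRNAs also altered any short RNA cannot be read from these values.

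The count of genes at an unadjusted p under 0.05 was set beside the other ways to split the 3 libraries into 1 and 2. The siRNA libraries against si-NC gave 293 genes, siRNA-1 against the other two gave 561 and siRNA-3 against the other two gave 1616. All 3 of the 3 splits gave at least as many genes as the labels' split, and 3 splits are too few for a share under 0.05. The counts with si-NC and with siRNA-1 alone lay below what evenly spread p-values would give, and that with siRNA-3 alone lay above. With the limma adjusted p, 0 genes passed in each of these splits. Among protein-coding genes 1 passed with si-NC as the lone library, 11 with siRNA-1 and 1 with siRNA-3. Among gene lists, 2 of 22 stood apart on the same side with si-NC as the lone library, and 5 did with siRNA-1 and 5 with siRNA-3. The G2 and M phase and interferon-stimulated lists also stood apart with siRNA-3 as the lone library. Among terms the counts were 3 with si-NC, 8 with siRNA-1 and 6 with siRNA-3.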
